A study of Danio rerio with 3 samples.

How the data were processed

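Brain tissue of zebrafish (Danio rerio) was profiled with a droplet method (10x Genomics), in which each transcript molecule carries a unique molecular identifier (UMI) and each droplet a barcode. The labels name 3 libraries: a control (Ctrl) and libraries from zinc treatments called Zn10 and Zn15. The unit of the numbers 10 and 15, the route and length of exposure, the age of the fish and the number of fish pooled per library are not given in the sources used here. Each treatment had 1 library. The labels say single cell. Whether whole cells or nuclei were loaded cannot be settled from the counts: malat1, a nuclear RNA, took 27.1% to 32.3% of UMIs and mitochondrial transcripts 0.091% to 0.211%, shares that nuclei can also give. Barcodes are therefore not called whole cells below, and values of mitochondrially encoded genes carry this doubt.

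The authors deposited UMI counts per gene and barcode, not normalised, as whole numbers. Per the file headers, the matrices were written by Cell Ranger 4.0.0. The submitters' processing notes also name fastp, Seurat and the genome build GRCz11. The cell calling settings, the annotation release and whether intronic reads were counted are not given in the sources used here. The deposited gene table pairs 32057 Ensembl gene identifiers with symbols, and 28988 of the identifiers were found in the gene name table used here. Where a symbol belongs to several identifiers, the identifier is given with the symbol. The feature CR383676.2 is paired with malat1, a nuclear non-coding RNA, in that table and is called malat1 here. No genome of the authors' build was used, so no coordinates are given. The gene order used in 1 test came from the RefSeq annotation of assembly GRCz12tu. Near-identical gene copies, such as hsp70.1, hsp70.2 and hsp70.3, share sequence, and the split of counts between them is uncertain.

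Depth was low. The libraries held 1698707 (Ctrl), 974866 (Zn10) and 1634806 (Zn15) UMIs in 5679, 2850 and 5154 barcodes, with medians of 240, 271 and 255 UMIs per barcode. A gene with no UMI in a library was given a floor of 3 counts, which is 1.77, 3.08 and 1.84 counts per 1000000 UMIs (CPM). Between 4 and 8 barcode sequences were shared by any pair of libraries.

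Barcodes with at least 100 genes and at most 30% mitochondrial UMIs were clustered, which kept 4629, 2459 and 4119 barcodes. Counts were scaled to 300 UMIs per barcode and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 nearest neighbours was partitioned by the Leiden method at resolution 1.0, over all 3 libraries together and without integration. Mitochondrial, ribosomal protein and haemoglobin genes and malat1 were left out of the clustering. The markers of 28 classes were fixed before the data were seen. The rule that applied them was not: it was set after the clusters, their leading genes and their shares per library had been looked at. By that rule a cluster was named for a class when at least 3 of its markers were 2-fold or more higher than in the other barcodes, with 15 or more UMIs each, at least 1 of them among the 10 leading genes, and more there than for any other class. The general neuron markers were not used for naming. By hand, and likewise after the data were seen, cluster 3 was left without the Purkinje neuron name because of barhl2, lhx9, zfhx3 and pou3f1, and cluster 12 without the microglia or macrophage name because of rgs13, ccr9a, ccl19a.1 and runx3. Of 18 clusters, 10 were named; the others keep their numbers. Clusters 9 and 15 were not compared in size, since their defining genes themselves differed between libraries by more than 0.58 in median log2. Genes that define a cluster are not named singly as results for it, but gene lists within classes keep such members.

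Scrublet, as in scanpy, called 2 of the barcodes doublets, 0.020% of all, and with so few calls it cannot be taken to have worked, so doublets were not removed. For a comparison at equal depth, barcodes were thinned to 200 UMIs, which kept 3539, 1990 and 3358 barcodes and left out 1090, 469 and 761 shallower ones in Ctrl, Zn10 and Zn15. Free RNA was not corrected, and RNA of abundant genes from other cells is part of every class total.

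Counts were summed over all barcodes of a library, or over the barcodes of a class, and expressed as CPM. With 1 library per treatment no test across samples is possible. No p-value was computed, and each ratio compares these libraries, not the conditions. Shares of barcodes carry exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. Spread between fish, dissociations and library preparations is not in them.

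Total-count scaling left the middle gene off 0. The median-of-ratios shift was 0.13 (Zn10 over Ctrl), −0.06 (Zn15 over Ctrl) and −0.18 (Zn15 over Zn10) on the log2 scale. Gene values are given as CPM ratios to be read against these shifts, and gene lists are reported relative to random lists that carry the same shift.

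The genes named were set by rule. For each pair of libraries, among genes with at least 50 UMIs, they were the 8 highest and the 8 lowest CPM ratios ranked by the interval bound nearest to 1, without mitochondrial, ribosomal protein, haemoglobin and clone-named genes. Within each of the 6 largest named classes, they were the 3 highest and the 3 lowest with at least 30 UMIs. For each list they were the 3 members with the most UMIs and the member with the largest ratio, and all metallothionein list members were named. There were 29 gene lists. A member counted as measured with at least 20 UMIs over the pair, and as higher or lower at 1.5-fold. A list with at least 3 measured members was summarised by its median log2 ratio minus the median of 10000 random lists of the same size matched on mean expression in 40 bins, called its excess here, with the percentile of its median among those random lists. Of a list standing at or under the 2.5th or at or over the 97.5th percentile it is said that it stood apart. Random lists are drawn gene by gene, whereas members of a list can move together, as mitochondrially encoded genes did in Zn10. Such a percentile describes where a list stood in these libraries and does not measure chance. The ribosomal protein list was taken by symbol and also holds rps6kc1 and rps19bp1, which are not ribosomal proteins.

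The changes in both zinc libraries were compared by their covariance and correlation across genes with at least 50 UMIs, beside 100 simulations with no change, since both ratios share the Ctrl library. The groups, markers, lists, designs and first set of alternatives were fixed before the data were examined. That set covered scaling, barcode filters, UMI minimums, variable genes, Leiden resolution and thinning. Scaling without malat1, leaving out the barcodes with the highest 5% of doublet scores, and clustering without stress genes or without genes 2-fold apart were added after the data were seen.

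The calculations were tested on simulated data. With 200 genes changed 2-fold or 4-fold in counts drawn for the 5105 genes of Zn10 over Ctrl, the interval covered the true ratio of 96.2% of unchanged and 96.0% of changed genes, and the median log2 ratio of genes raised 2-fold was 0.97 and of genes raised 4-fold 1.97. For Zn15 over Ctrl (5602 genes) these were 96.1%, 96.0%, 0.97 and 1.98. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used.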

Results

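The brain single-cell libraries addressed how zinc acts on the zebrafish brain. The comparisons were Zn10 with Ctrl, Zn15 with Ctrl, and Zn15 with Zn10, each 1 library against 1 library. Ctrl held 1698707 UMIs in 5679 barcodes, Zn10 974866 UMIs in 2850 and Zn15 1634806 UMIs in 5154. Median depth was 240 UMIs and 145 genes per barcode in Ctrl, 271 and 164 in Zn10, and 255 and 146.5 in Zn15. The nuclear RNA malat1 took 29.3% (95% interval 29.2 to 29.4), 27.1% (27.0 to 27.1) and 32.3% (32.2 to 32.4) of all UMIs in Ctrl, Zn10 and Zn15. Mitochondrial transcripts made up 0.211%, 0.091% and 0.206% of UMIs, and haemoglobin genes gave 2, 2 and 9 UMIs.

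Clustering gave oligodendrocyte-like, oligodendrocyte precursor-like, microglia or macrophage-like, radial glia-like, glutamatergic neuron-like, GABAergic neuron-like, cerebellar granule neuron-like, newborn neuron or progenitor-like and dividing cell-like classes. Radial glia-like barcodes came from clusters 10 and 17, and every other class was 1 cluster. The inflammatory genes il1b and cxcl8a were among the leading genes of the microglia or macrophage-like cluster, and the activity-regulated genes bdnf and npas4a among those of the glutamatergic neuron-like cluster. Unnamed clusters 1 and 3 held 13.3% and 10.3% of the kept Ctrl barcodes.

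Which cell classes were more or less frequent was asked first. Microglia or macrophage-like barcodes made up 8.92% of kept barcodes in Ctrl (8.12 to 9.78) and 4.84% in Zn10 (4.03 to 5.76), a ratio of 0.542 (0.439 to 0.667), and 7.94% in Zn15 (7.13 to 8.81). Oligodendrocyte-like barcodes, which carry the myelin genes, were at 13.3% in Ctrl (12.3 to 14.3), 9.31% in Zn10 (8.19 to 10.5) and 10.1% in Zn15 (9.20 to 11.1). Their precursors were at 6.22% (5.54 to 6.96), 9.44% (8.31 to 10.7) and 7.45% (6.67 to 8.30). With at least 200 genes per barcode the precursor ratio in Zn10 went from 1.52 to 1.202 (0.944 to 1.53) and in Zn15 from 1.198 to 1.11 (0.885 to 1.39), and the oligodendrocyte-like ratio in Zn15 from 0.759 to 0.836 (0.677 to 1.03), intervals that include 1. Glutamatergic neuron-like barcodes held 8.92% in Ctrl, 8.78% in Zn10 and 5.97% in Zn15, and GABAergic neuron-like barcodes 7.11%, 7.69% and 4.22%.

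In Zn15 glutamatergic neuron-like and GABAergic neuron-like barcodes, as named here, were below Ctrl, with ratios of 0.669 (0.569 to 0.786) and 0.594 (0.492 to 0.716). In Zn10 these classes stood at 0.985 (0.831 to 1.16) and 1.08 (0.899 to 1.30). Dividing cell-like barcodes rose from 7.09% in Ctrl to 8.74% in Zn15, a ratio of 1.23 (1.06 to 1.44), and radial glia-like barcodes from 5.27% to 6.87%, a ratio of 1.30 (1.09 to 1.55), beside 4.88% in Zn10, a ratio of 0.926 (0.738 to 1.16). At halved resolution the radial glia-like class held 34, 37 and 72 barcodes, with ratios of 2.05 (1.25 to 3.36) in Zn10 and 2.38 (1.56 to 3.69) in Zn15. That was no longer the same set of barcodes. In the main clustering cluster 17 held 33, 37 and 67 barcodes and cluster 10 held 211, 83 and 216. Most of cluster 10 thus lay outside the class at halved resolution, whereas the main ratios join both clusters. Cerebellar granule neuron-like barcodes were at 3.28% in Ctrl, 4.39% in Zn10 and 4.37% in Zn15, and with 1000 variable genes their ratios of 1.34 and 1.33 became 1.06 (0.860 to 1.31) and 1.11 (0.930 to 1.33). Newborn neuron or progenitor-like barcodes were at 2.81%, 2.93% and 3.08%, a difference not detectable at this depth. Among unnamed clusters, cluster 12, led by rgs13, ccr9a and runx3, held 1.82%, 3.05% and 4.25%. Cluster 16, led by ackr3a, cxcl12b and flt1, held 0.951%, 2.16% and 2.06%, with ratios of 2.27 and 2.17 that were 6.82 and 6.43 with at least 200 genes per barcode and 1.88 (0.961 to 3.69) and 1.35 (0.714 to 2.57) with 1000 variable genes. The ratio of cluster 12 in Zn10, 1.68, was 3.23 with at least 200 genes. Cluster 14, led by gpr139 and kiss1, held 2.66%, 3.95% and 1.92%, and with at least 200 genes its ratios were 1.51 (0.949 to 2.40) and 0.659 (0.382 to 1.12). Cluster 1 was at 13.3%, 13.3% and 15.5%, and its ratio of 1.17 in Zn15 became 0.952 with 1000 variable genes. Clusters 3 and 18 were at 10.3%, 10.4% and 9.49%, and at 0.497%, 0.691% and 0.437%.

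These shares depend on a naming rule set after the data were seen, which kept clusters with at least 3 markers of a class out of it. Cluster 1 carried 5 glutamatergic neuron markers, and with it that class held 22.19%, 22.04% and 21.44% in Ctrl, Zn10 and Zn15, so the lower share in Zn15 rests on leaving cluster 1 out. Cluster 12 carried 5 microglia or macrophage markers, and with it that class held 10.7%, 7.89% and 12.2%, still lower in Zn10 but above Ctrl in Zn15. Radial glia-like barcodes with cluster 16 held 6.22%, 7.04% and 8.93%, and with cluster 18 5.77%, 5.57% and 7.31%. Cerebellar granule neuron-like barcodes with cluster 14 held 5.94%, 8.34% and 6.29%, and with cluster 1 16.5%, 17.6% and 19.8%. Newborn neuron or progenitor-like barcodes with cluster 1 held 16.1%, 16.2% and 18.5%, and with cluster 3 13.1%, 13.3% and 12.6%. Oligodendrocyte precursor-like barcodes with cluster 9 held 11.8%, 13.4% and 12.3%, which are not compared, since the genes that define cluster 9 differed between libraries. Cluster 3 carried 3 Purkinje neuron markers.

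Shares depend on which barcodes pass the filter of 100 genes, and kept barcodes were deeper in both zinc libraries, with medians of 271 UMIs in Ctrl, 301 in Zn10 and 296 in Zn15. At an equal depth of 200 UMIs the ratios were 0.517 for microglia or macrophage-like barcodes in Zn10, 0.757 for glutamatergic neuron-like and 0.712 for GABAergic neuron-like barcodes in Zn15, and dividing cell-like barcodes were at 10.5% in Ctrl and 15.7% in Zn15.

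**Figure D1:**
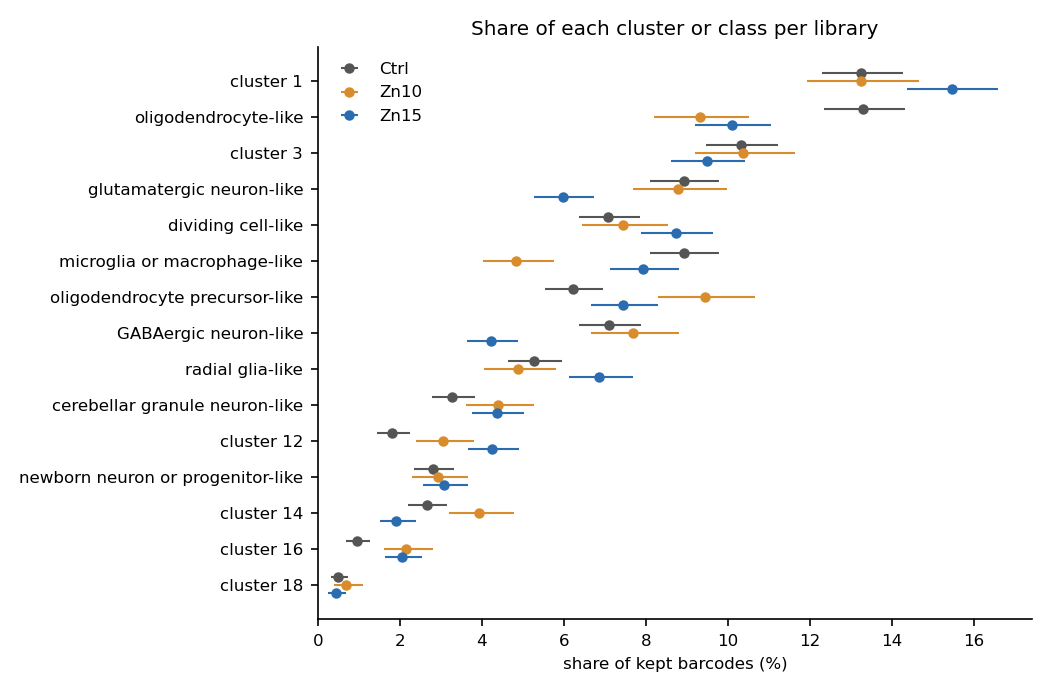
Share of kept barcodes (%, horizontal axis) in each cluster or class, with points for Ctrl, Zn10 and Zn15 and bars for exact 95% binomial intervals, which cover counting error only. Microglia or macrophage-like barcodes were at 4.84% in Zn10 against 8.92% in Ctrl, and GABAergic neuron-like barcodes at 4.22% in Zn15 against 7.11% in Ctrl.

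The next comparison asked which transcripts differed between Zn10 and Ctrl in whole libraries. The metallothionein gene mt2 (ENSDARG00000041623), whose product binds zinc and whose transcription zinc is known to induce, stood at 896 CPM in Ctrl and 478 CPM in Zn10, a log2 ratio of −0.91 (ratio 0.480 to 0.592). Its UMIs were concentrated, with 44.0%, 64.4% and 48.3% of them in the highest 1% of barcodes of Ctrl, Zn10 and Zn15. Only 598, 155 and 341 barcodes had any. The intervals treat UMIs as independent and are too narrow for such a gene. The heat-inducible chaperone gene hsp70l was at 6663 CPM in Ctrl and 4307 CPM in Zn10 (log2 −0.63). Major histocompatibility class II gene mhc2dab rose from 30.6 to 199 CPM (log2 2.70, ratio 4.76 to 9.01), and olig2, a transcription factor of the oligodendrocyte lineage, from 168 to 552 CPM (log2 1.72, ratio 2.84 to 3.81). Of the genes on the low side, rag2, a recombinase of lymphocyte development, gave 143 UMIs in Ctrl and 0 in Zn10, a log2 ratio of −4.77 or lower at the floor of 3 counts.

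Also higher in Zn10 was fgf1a, a growth factor (log2 2.71, 16 and 60 UMIs). Lower in Zn10 were ehbp1l1b (−3.90, 78 and 3 UMIs), the iron hormone gene hamp (−2.17, 47 and 6 UMIs), efemp2b (−2.20), stoml3b (−2.11), the endosomal sorting gene tsg101b (−2.06), the amino acid transporter slc7a3b (−1.74), kif13ba (−1.68) and n4bp1 (−1.56). The opsin gene exorh (log2 8.73) gave 243 UMIs in Zn10 from 12 barcodes, and 87.0% of the aldoca UMIs in Zn10 (log2 5.65) lay in 1 barcode. For pde6gb (2.25) and pvalb7 (2.39) 1 barcode held 42.9% and 52.9% of the Zn10 UMIs, so these 4 values rest on few barcodes.

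Among the gene lists in Zn10, mitochondrially encoded genes stood lowest. All 11 measured members were at least 1.5-fold lower, with mt-co1 at 393 and 181 CPM, mt-co2 at 510 and 222 CPM and mt-co3 at 405 and 158 CPM in Ctrl and Zn10, and the excess over random lists was −1.29 (percentile 0.0). The myelin list had an excess of −0.51 (percentile 0.01), 5 of 12 members lower, with mbpa at −1.25 and plp1b at −0.93, beside the lower share of oligodendrocyte-like barcodes. In Zn15 that share had a ratio of 0.759, against 0.7 in Zn10, while the myelin list stood at −0.10 (percentile 18.0). Within classes of at least 20 UMIs, mbpa was lower in 4 of 4 and plp1b in 6 of 8 in Zn10, and in 8 of 9 and 4 of 5 in Zn15. The middle cluster held only 0.00594 (mbpa) and 0.00338 (plp1b) of the level of the highest cluster. Their UMIs in other classes may thus be free RNA, and the classes do not count as separate observations. Heat shock proteins stood at −0.25 (percentile 0.44), with hsp90aa1.2 at −0.43 and hsp70.3 at −0.31; 2 of 20 members were lower and 2 higher. With clusters reweighted to the Ctrl mix the list was at −0.13 (percentile 5.38) and no longer stood apart. Endoplasmic reticulum stress genes stood at −0.24 (percentile 0.645), with hspa5 at −0.36 and manf at −0.25 against trib3 at 0.85. Apoptosis and p53 targets stood at −0.22 (1.43), with mcl1b at −0.46 and ccng1 at −0.53 and none of 24 members past 1.5-fold, and no longer stood apart with members of at least 5 UMIs (3.29) or barcodes of at least 200 genes (2.69). Antigen presentation stood at −0.38 (0.79), with mhc1zba at −1.42 and mhc1uba at −1.03 against mhc2dab, beside the lower share of microglia or macrophage-like barcodes. However, mhc1zba and mhc1uba were lower in all of the 14 largest clusters where they were measured. Cholesterol synthesis stood at −0.37 (1.12), with ldlra at 84 and 21 UMIs and dhcr7 at −0.69 against hmgcra at 0.49; with members of at least 5 UMIs it was at −0.16 (17.1), and with at least 100 UMIs it turned to 0.0137 (54.0). Ribosomal proteins stood at −0.17 (0.0), although 82 of 87 were within 1.5-fold. Glutamate receptors were the list standing apart on the high side, with an excess of 0.41 (99.7), 6 of 13 members higher, gria4a at 1.14 and gria2b at 0.67.

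The same comparison was made for Zn15. Zinc-binding mt2 stood at 408 CPM against 896 CPM in Ctrl (log2 −1.13, ratio 0.415 to 0.499), and hsp70l at 3362 against 6663 CPM (log2 −0.99, ratio 0.489 to 0.521). The vesicle transport gene rab1ba (ENSDARG00000058044) rose from 161 to 579 CPM (log2 1.84, ratio 3.13 to 4.12), and aplp2 (ENSDARG00000054864), a relative of the amyloid precursor gene, from 231 to 886 CPM (log2 1.94, ratio 3.42 to 4.29). Chromatin gene nucks1a (ENSDARG00000078473) was at 1283 CPM in Ctrl and 444 CPM in Zn15 (log2 −1.53, ratio 0.318 to 0.377). All 3 were on the same side in Zn10, with log2 ratios of 1.44, 1.58 and −1.28.

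Also higher in Zn15 were mhc2dab (2.92), the matrix gene dcn (2.43, 10 and 52 UMIs), tspan17 (2.15) and the sialomucin gene cd164 (1.98). The rrm2 copy ENSDARG00000078069, which codes for a subunit of ribonucleotide reductase, had 0 UMIs in Ctrl and 76 in Zn15, a log2 ratio of at least 4.72 at the floor. Lower in Zn15 were rag2 (143 and 2 UMIs, ratio 0.0145 with an interval of 0.00174 to 0.0535), hamp (−2.33), ppdpfa (−2.17), efemp2b (−1.94), oaz2b (−1.84), the sodium pump subunit atp1b1b (−1.78, from 352 to 103 CPM) and trappc12 (−1.70).

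**Figure D2:**
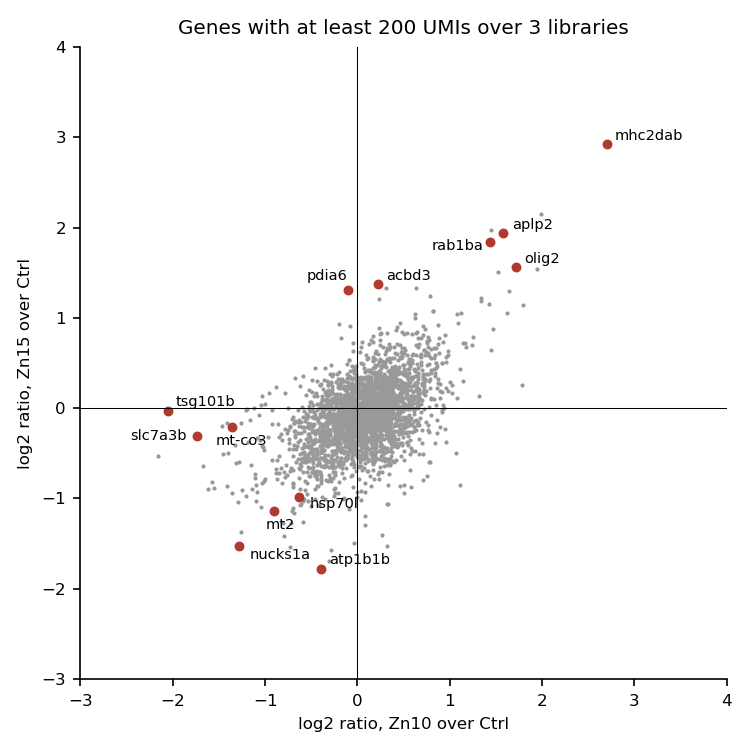
Each point is a gene with at least 200 UMIs over the 3 libraries (2707 genes, 1 of them outside the axes), with its log2 CPM ratio of Zn10 over Ctrl on the horizontal axis and of Zn15 over Ctrl on the vertical axis. Named genes are in red; mt2 lies at −0.91 and −1.13, and rab1ba at 1.44 and 1.84.

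Heat shock proteins again stood apart in Zn15, with an excess of −0.24 (percentile 0.63), 4 of 22 members lower and 2 higher, the latter including serpinh1b at 1.40. Cell cycle genes stood at 0.40 (99.925), with 8 of 23 members higher and mki67 at 0.90, beside the higher share of dividing cell-like barcodes, and at percentile 91.0 with members of at least 100 UMIs. Inflammation genes stood at 0.29 (99.4) with 5 of 16 higher, although il1b was at 0.13 and nfkbiaa at −0.04, and the small-count gene mmp13a ENSDARG00000114451 (4 and 22 UMIs) had the largest ratio of the list; the list no longer stood apart with barcodes of at least 200 genes (95.6) or members of at least 100 UMIs (65.2). Interferon response genes stood at 0.33 (97.8), with irf7 at 24 and 53 UMIs, stat2 at 0.47 and b2m at 0.68, and fell below the limit under 4 other settings, at 97.0 to 97.4. Antigen presentation stood at 0.32 (98.5) through mhc2dab, b2m and b2ml (0.36), while mhc1zba was at −0.86, and no longer stood apart with barcodes of at least 200 genes (76.0) or members of at least 5 UMIs (94.7). Ribosomal proteins stood at 0.23 (100), with rpl12 at 0.44 and rpl6 at 0.31. Glutamate receptors stood at −0.34 (1.11), with grm1a at −1.04 and grin1b at −0.36, and transmitter synthesis and transport at −0.31 (1.005), with gad2 at −0.63 and slc6a1b at −0.32, beside the lower shares of glutamatergic neuron-like and GABAergic neuron-like barcodes as named here. With members of at least 100 UMIs these 2 lists were at percentiles of 39.3 and 3.195, and with barcodes of at least 200 genes glutamate receptors were at 7.72, so neither call held throughout. Mitochondrially encoded genes were at an excess of 0.07 (71.3).

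**Figure D3:**
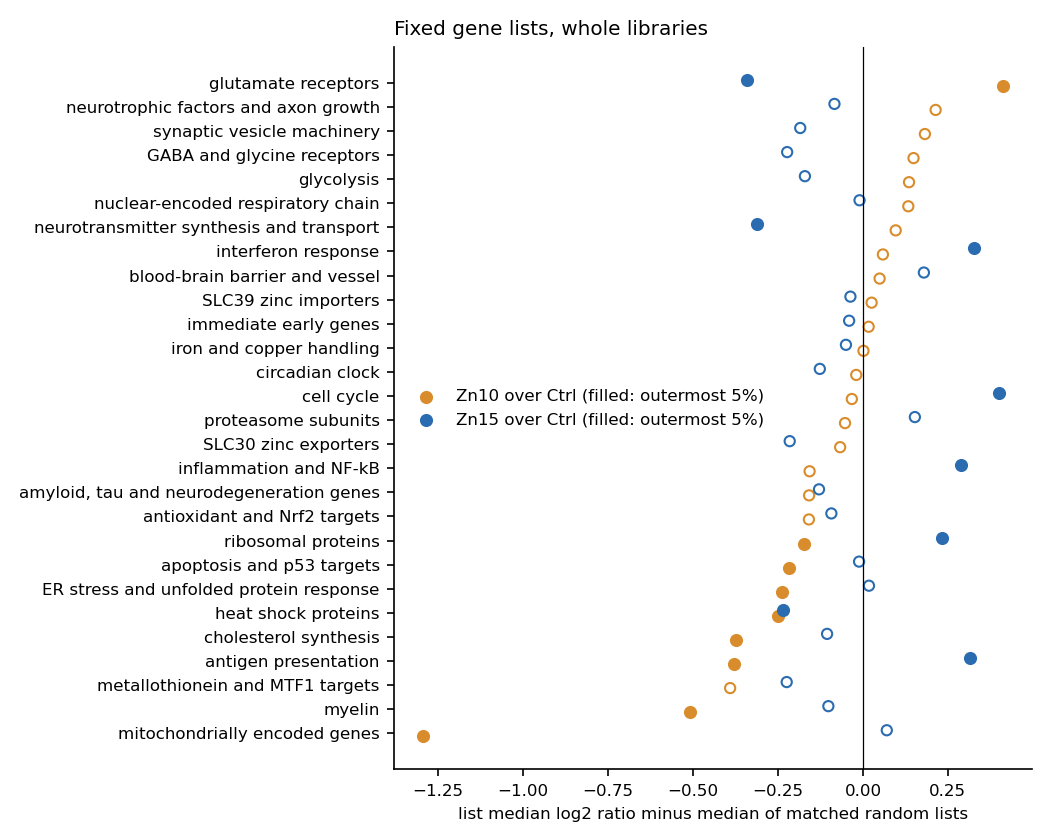
Excess of each gene list (median log2 ratio of the list minus the median of matched random lists, horizontal axis) in Zn10 and Zn15 over Ctrl, with filled points for the outermost 5% of random lists. Mitochondrially encoded genes lie at −1.29 in Zn10 and 0.07 in Zn15, and heat shock proteins at −0.25 and −0.24.

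Of 28 lists with enough members, 9 stood apart in Zn10 (8 low, 1 high) and 8 in Zn15 (3 low, 5 high). The others lay within the range of random lists at the settings used here, given here as the excess in Zn10 and in Zn15. Synaptic vesicle machinery stood at 0.18 and −0.18, with snap25a at 0.02 and −0.64 and stxbp1a at 0.26 and −0.40, at percentiles of 97.3 and 2.66. Under other settings it stood apart, in Zn10 by median of ratios (97.6) and with members of at least 5 UMIs (98.1), and in Zn15 without malat1 in the total (2.37), with barcodes of at least 200 genes (−0.67, percentile 0.0) and with members of at least 100 UMIs (−0.33, percentile 0.03). GABA and glycine receptors stood at 0.15 and −0.22, neurotrophic and axon growth genes at 0.21 and −0.08, with tubb5 at 0.54 and 0.27, and glycolysis genes at 0.14 and −0.17, with pkma at 0.05 and −0.52. Immediate early genes, which respond to neuronal activity and to tissue handling, stood at 0.02 and −0.04, with jun at −0.02 and −0.18, fosab at 0.31 and −0.17 and npas4a at 0.63 and −0.24. Antioxidant genes stood at −0.16 and −0.09, with sqstm1 at −0.09 and 0.14 and nfe2l2a at −0.93 and −0.17. Amyloid, tau and neurodegeneration genes stood at −0.16 and −0.13, with appa at 0.26 and 0.03, maptb at 0.26 and −0.20 and the lysosomal protease gene ctsba at −0.89 and −0.67. Nuclear-encoded respiratory chain genes stood at 0.13 and −0.01, with ndufb2 at −0.70 and −0.84, proteasome subunits at −0.05 and 0.15, circadian clock genes at −0.02 and −0.13, with per1b at 0.32 and −0.94, and iron and copper handling genes at 0.00 and −0.05, with fth1a at 0.11 and 0.13. Vessel and barrier genes stood at 0.05 and 0.18, with tjp1a at 0.14 and 0.40. Inflammation, interferon response, cell cycle and transmitter synthesis genes stood at −0.16, 0.06, −0.03 and 0.10 in Zn10, and endoplasmic reticulum stress, apoptosis, cholesterol synthesis and myelin genes at 0.02, −0.01, −0.11 and −0.10 in Zn15. With barcodes of at least 200 genes, glycolysis (−0.28), neurotrophic (−0.31) and circadian genes (−0.29) stood apart in Zn15, and with members of at least 100 UMIs neurotrophic genes in Zn10 (0.28) and vessel and barrier genes in Zn15 (0.44). No haemoglobin gene reached the minimum.

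The genes of zinc handling were followed member by member. Besides mt2, the second metallothionein gene mtbl gave 35, 15 and 22 UMIs in Ctrl, Zn10 and Zn15 (log2 −0.42, ratio 0.379 to 1.40, and −0.61, ratio 0.365 to 1.15). The zinc exporter slc30a1a, another known target of the zinc sensor MTF1, was at 129, 104 and 110 CPM (log2 −0.32, ratio 0.628 to 1.02, and −0.23, ratio 0.697 to 1.04). The transporter slc39a10 was at 0.16 and 0.06, slc30a5 at −0.01 and −0.29, and mtf1 itself gave 11, 3 and 5 UMIs. No UMI of slc30a1b was counted in any library. As a list, metallothionein and MTF1 target genes had an excess of −0.39 (percentile 7.07) in Zn10 and −0.22 (16.3) in Zn15. With barcodes of at least 200 genes it came to stand apart in Zn10, at −0.76 (1.29). Zinc exporters of the SLC30 family stood at −0.07 (43.1) and −0.22 (19.4), and importers of the SLC39 family at 0.03 (54.0) and −0.04 (45.3).

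In classes, mt2 was below Ctrl in 11 of 13 classes in Zn10 and 11 of 14 in Zn15 with at least 20 UMIs. It stood at 1000.1 CPM in Ctrl, 176 in Zn10 and 481 in Zn15 in glutamatergic neuron-like barcodes and at 932, 246 and 532 in GABAergic neuron-like barcodes. The Zn15 values rest on few barcodes, 8 with 41.5% of the mt2 UMIs in 1 of them and 15 with 51.4% in 1, and the Zn10 values on 9 and 10 barcodes. The radial glia-like class mixed its clusters differently, with cluster 17 giving 20% of its UMIs in Ctrl, 48.2% in Zn10 and 32.8% in Zn15. In cluster 10 mt2 gave 59, 1 and 13 UMIs (ratios 0.00108 to 0.252 and 0.0946 to 0.347), and in cluster 17 24, 13 and 41 UMIs (ratios 0.175 to 0.764 and 0.441 to 1.29). In oligodendrocyte-like barcodes it was at 183, 207 and 253 CPM, with intervals of the ratio that included 1. The gene hsp70l was lower in 14 of 17 classes in Zn10 and 17 of 17 in Zn15. The heat shock list stood below random lists in 13 of 17 classes in Zn10 and 15 of 17 in Zn15, apart from them in 9 and 11. Its excess was −0.60 and −0.59 in GABAergic neuron-like, −0.24 and −0.66 in glutamatergic neuron-like, −0.42 and −0.27 in oligodendrocyte-like barcodes, and 0.02 and −0.03 in microglia or macrophage-like barcodes.

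**Figure D4:**
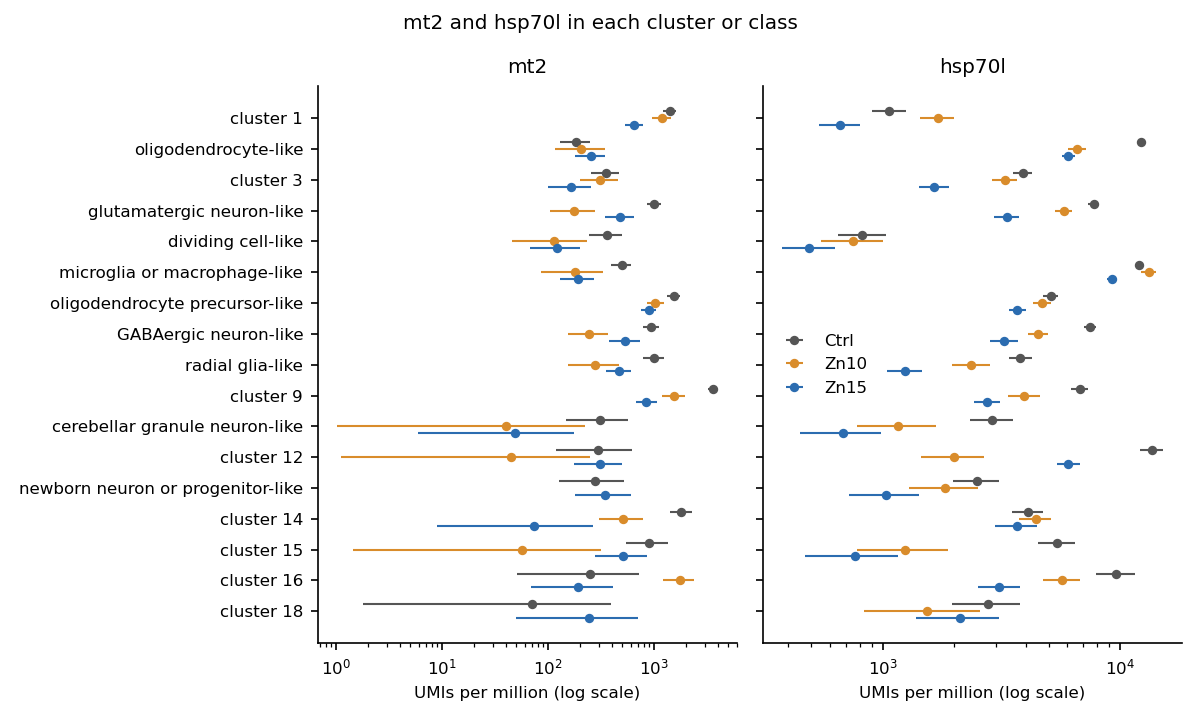
CPM (horizontal log axis) of mt2 and hsp70l in each cluster or class, with points for Ctrl, Zn10 and Zn15 and bars for exact 95% Poisson intervals, which cover counting error only; a class with no UMI has no point. In glutamatergic neuron-like barcodes mt2 lies at 1000.1 CPM in Ctrl, 176 in Zn10 and 481 in Zn15.

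Within classes, the genes with the largest ratios were often the same in several of them. In every class with at least 20 UMIs, rab1ba and aplp2 were higher in both zinc libraries (10 and 11 classes in Zn10, 15 and 14 in Zn15), and nucks1a was lower (14 and 14). The ubiquitin enzyme gene ube2al was higher in 15 of 16 and 15 of 17 classes, with log2 ratios in Zn10 of 2.22 in microglia or macrophage-like, 1.87 in GABAergic neuron-like, 1.67 in oligodendrocyte precursor-like and 1.48 in oligodendrocyte-like barcodes. In oligodendrocyte-like barcodes olig2 stood at 633, 3348 and 2167 CPM in Ctrl, Zn10 and Zn15. In microglia or macrophage-like barcodes mhc2dab stood at 78.2, 2284 and 1735 CPM, while the lysosomal protease gene ctsla fell by 1.60 and by 1.63 on the log2 scale, and itga5 and hamp were at −2.16 and −2.34 in Zn15. The copy mmp13a ENSDARG00000114451, a collagenase gene, gave 0 UMIs in Ctrl and 30 in Zn10 in that class, from 6 barcodes.

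Further class values followed the same rule. In glutamatergic neuron-like barcodes limk2 was at 1.72, smu1b at −3.06 and plk3 at −1.24 in Zn10, and mctp1a at 2.27 and hspa4a at −1.65 in Zn15; exorh and pde6gb there came from 2 and 4 Zn10 barcodes. In GABAergic neuron-like barcodes tuba1c was at 1.60 and slc7a3b at −1.82 in Zn10, and atp2a3 at 2.06, chgb at 2.37 and sec61a1 at −1.88 in Zn15; 1 barcode held 31.1% of the atp2a3 and 42.9% of the chgb UMIs there. Dividing cell-like barcodes had dnajb1b at 2.83, trib3 at 2.36, adgre10 at 2.32, zfhx4 at −2.63 and cs at −1.15 in Zn10, and ino80 at 2.06, pdia6 at 2.51, egr4 at 2.08, dnajc9 at −2.28 and pdk2a at −2.06 in Zn15. Oligodendrocyte precursor-like barcodes had mbd3b at 1.90, pacsin1a at −1.80 and id2b at −1.77 in Zn10, and acsl1a at 2.04, scarb1 at −2.04 and rflnb at −1.49 in Zn15. In oligodendrocyte-like barcodes ctnnd1 was at −3.41 in Zn10 and cd164 at 2.54 and sox11a at −3.04 in Zn15, and 52.0% of the epd UMIs in Ctrl (log2 −3.86 and −3.55) lay in 1 barcode.

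The 2 zinc libraries were also set against each other. Mitochondrially encoded genes stood higher in Zn15 than in Zn10, with an excess of 1.32 (percentile 100) and 11 of 11 members at least 1.5-fold higher. Among neuronal lists, synaptic vesicle machinery stood apart on the low side, with an excess of −0.53 (0.0), 12 of 22 members lower and snap25a at −0.66. So did glutamate receptors at −0.74 (0.0), with 10 of 14 lower, and transmitter synthesis and transport at −0.42 (0.200). GABA and glycine receptors and neurotrophic and axon growth genes were also below random lists, but within their range at the settings used here. Antigen presentation (0.55), inflammation (0.33), interferon response (0.43), cell cycle (0.49), myelin (0.47), ribosomal proteins (0.38) and apoptosis and p53 targets (0.22) stood apart on the high side. With barcodes of at least 200 genes, interferon response (95.2), apoptosis (96.3) and transmitter synthesis and transport (47.5) no longer did, and with members of at least 100 UMIs interferon response (96.0), cell cycle (85.0) and transmitter synthesis and transport (19.6) did not. These lists stand beside share ratios of Zn15 over Zn10, for classes as named here, of 0.680 (0.564 to 0.820) for glutamatergic neuron-like, 0.550 (0.445 to 0.679) for GABAergic neuron-like and 1.64 (1.33 to 2.04) for microglia or macrophage-like barcodes. The glutamatergic ratio rests on leaving cluster 1 out, since with it that class held 22.04% in Zn10 and 21.44% in Zn15. Among genes, ehbp1l1b (3.80), the rrm2 copy ENSDARG00000078069 (8 and 76 UMIs), slc43a1a (2.09), tsg101b (2.03), the retinoic acid hydroxylase gene cyp26b1 (11.3 and 45.3 CPM), slc7a3b (1.43), the disulfide isomerase gene pdia6 (1.41) and acbd3 (1.16) were higher in Zn15. The neuropeptide genes sst1.1 (−3.01) and npy (−2.49), ppdpfa (−2.29) and syt13 (−1.97) were lower; npy came from 10 and 8 barcodes.

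The covariance of the changes in both zinc libraries lay above that from the shared control's counting error. Across 6520 genes the covariance of the log2 ratios was 0.153 against 0.0408 simulated without change, a difference of 0.112, and the correlation across genes, which are not independent replicates, was 0.526 against 0.421 simulated. With the Ctrl barcodes split at random into 2 parts, 1 per ratio, the difference was 0.107. Within classes it ranged from 0.0803 in oligodendrocyte precursor-like to 0.240 in microglia or macrophage-like barcodes. The correlation did not exceed the highest simulated one in glutamatergic neuron-like (0.390 against 0.439) and oligodendrocyte precursor-like barcodes (0.566 against 0.569). In whole libraries 64.6% of genes lay on the same side of the median in both, against 63.9% simulated. Both ratios share 1 Ctrl library, so part or all of this may come from that library. Splitting its barcodes takes away shared counting error only, since both parts are still of that library.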

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

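Chosen only after the result was seen were the tests of immediate early genes, of linked haplotype blocks, of the malat1 share and of mitochondrial sequence variants, and the spread from redrawing list members or UMIs that was set beside the other test values. For immediate early genes, linked haplotype blocks and the malat1 share, the rule for calling the outcome was then made stricter. That moved each from argued against to open, with unchanged values. The spread treats list members as independent of each other. The list values below are excesses over random lists on the log2 scale.

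The metallothionein gene mt2 and the heat shock list were lower in both zinc libraries, the reverse of the known induction of mt2 by zinc. A few barcodes with very high levels were argued against. Without the highest 1% of barcodes of each library, mt2 stood at −1.26 (spread −1.44 to −1.07) in the zinc library nearer to 0. The list likewise stood at −0.24 (−0.48 to −0.15). For mt2, different shares of the clusters were argued against too, at −1.06 (−1.23 to −0.90) with clusters reweighted to the Ctrl mix. That does not reach different kinds of barcodes within a cluster, which stay open. The level of mt2 was highest in cluster 9, at 2072 CPM over all libraries, and the genes that define cluster 9 differed between libraries. For the list, reweighting moved the excess from −0.25 to −0.13 (−0.28 to −0.05, percentile 5.38) in Zn10 and from −0.22 to −0.16 (percentile 1.86) in Zn15, both past the bound of −0.12 set beforehand, but the spread, added after these values were seen, reached over that bound and leaves class shares open as a part of it. A handling response of the Ctrl library with immediate early genes stays open, since their percentile was 30.2 in the lower zinc library and their excess was 0.02 (−0.25 to 0.12) in Zn10 and −0.04 (−0.19 to 0.14) in Zn15. Heat alone during preparation of the Ctrl library, exchanged labels, which these data cannot check, and zinc itself stay open, untested.

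Some genes differed alike in all of the 14 largest clusters where they were measured, by a median of at least 2-fold. In Zn10 these were 17 higher and 18 lower of 2161 genes, and in Zn15 10 and 19 of 2423. Libraries simulated with counting error alone gave at most 2. The lower genes include mt-co1, mt-co2, mt-atp6 and mt-co3 in Zn10 and hsp70l in Zn15, so this pattern partly repeats the mitochondrial and heat shock patterns. Free RNA from 1 cell class stays open. In the median gene the middle cluster held 0.318 (0.270 to 0.417) of the level of the highest cluster. This ratio was 0.00338 for the oligodendrocyte gene plp1b and 0.0106 for the GABAergic gene gad2. But genes entered only with at least 10 UMIs in at least 6 clusters, which itself favours broadly counted genes. The ratio of the other genes that entered was not computed, so the test cannot decide. Linked blocks of the genome that differ between the fish stay open, since 11 of 51 placed genes had another within 50 genes, within the range of random sets (median 10), and zbtb1, srsf5b, id2b, acbd3 and cd164 lay near each other. Genotype differences at single genes, differences between library preparations and zinc itself stay open, untested.

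Mitochondrially encoded RNA was lower in Zn10 and not in Zn15. Shallow barcodes were argued against by an excess of −1.63 (−2.09 to −1.13) among barcodes with at least 200 genes. That filter goes by gene number alone and cannot tell damaged barcodes, which stay open. Sequence variants that stop some genes from being counted were argued against, since the measured member nearest to 0 stood at −0.96 and the lowest at −3.29. A larger share of nuclear RNA stays open. The malat1 share had a ratio of 0.923 (0.918 to 0.927) to Ctrl in Zn10, lower where this explanation needs it higher. But in Zn15 the malat1 share was higher without lower mitochondrial RNA. It thus did not follow mitochondrial RNA there and cannot decide the question. A difference in dissociation or library preparation and zinc itself stay open, untested.

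Other differences between groups or between classes were seen and were not tested. Values of clusters 9 and 15 carry the limit that the genes that define these clusters differed between libraries, so their barcodes need not be of the same kind in each. The differences were picked out of 212 list and class values in Zn10 and 239 in Zn15, besides the whole-library lists. Between the zinc libraries, antigen presentation stood on opposite sides of Ctrl, at −0.38 in Zn10 and 0.32 in Zn15. So did glutamate receptors, at 0.41 and −0.34, the latter −0.0399 with members of at least 100 UMIs, and ribosomal proteins, at −0.17 and 0.23. Between classes in Zn10, glycolysis genes ranged from −0.76 in cluster 9 to 0.66 in cluster 14. Heat shock proteins ranged from −2.08 in cluster 12 to 0.30 in cluster 1, and immediate early genes from −1.03 in cluster 15 to 0.81 in cerebellar granule neuron-like barcodes. Ribosomal proteins there ranged from −0.36 in cluster 3 to 0.91 in cluster 12.

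Between classes in Zn15, cholesterol synthesis genes ranged from −0.51 in radial glia-like barcodes to 1.18 in cluster 9, a difference that was not tested. The radial glia-like value mixes clusters 10 and 17 in different proportions, and cluster 10 alone stood at −0.26 (percentile 12.6), and cluster 9 carries the limit given above. Immediate early genes ranged from −0.47 in cluster 1 to 0.51 in cluster 14, and mitochondrially encoded genes from −0.83 in microglia or macrophage-like barcodes to 1.79 in cluster 18. Ribosomal proteins ranged from −0.28 in GABAergic neuron-like barcodes to 0.49 in cluster 12.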

How the results depend on the processing

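With 1 library per treatment, no alternative speaks to the spread between fish, and intervals cover counting error only. No paired analysis was possible because the labels pair no libraries. Scaling without malat1, the doublet score filter and clustering without stress genes or without genes 2-fold apart were chosen after the data were seen, as was the rule for naming clusters, under which shares are given with the clusters it kept out. The cause was not tested for any value below.

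Only kept barcodes had median UMIs of 271, 301 and 296. With at least 200 genes per barcode (1444, 1006 and 1404 barcodes), share ratios in Zn10 were 0.495 for oligodendrocyte-like, 1.202 (0.944 to 1.53) for oligodendrocyte precursor-like, 3.23 for cluster 12 and 6.82 for cluster 16. In Zn15 they were 1.38 for cluster 1, 0.521 for glutamatergic neuron-like, 1.63 for dividing cell-like, 0.462 for GABAergic neuron-like, 1.605 for radial glia-like and 6.43 for cluster 16. With 1000 variable genes they were 0.952 for cluster 1, which reversed, and 1.35 for cluster 16 in Zn15. Dividing cell-like barcodes in Zn15 stood at 1.497 thinned to 200 UMIs, and radial glia-like barcodes at 2.38 at halved resolution, where they were 34, 37 and 72 barcodes and the Zn10 ratio went from 0.926 to 2.05. Those counts are near the 33, 37 and 67 of cluster 17 alone, so most of cluster 10 lay outside the class there. No value was given for GABAergic neuron-like barcodes at halved resolution, cerebellar granule neuron-like barcodes with at least 200 genes and thinned, or cluster 16 thinned. Newborn neuron or progenitor-like barcodes had none with 4000 variable genes, with at least 200 genes, without genes 2-fold apart, without the highest doublet scores, at halved resolution and thinned.

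The median log2 ratio over genes was −0.0478 (Zn10 over Ctrl, reversed), −0.0107 (Zn15 over Ctrl) and 0.0428 (Zn15 over Zn10, reversed) by median of ratios, 0.0390, −0.00718 and −0.0328 without malat1, and 0.16, 0.0553 (reversed) and −0.16 with no minimum. It was −0.0514 for Zn15 over Ctrl with at least 200 genes, and −0.12 for Zn15 over Zn10 with at least 200 UMIs. Reversed genes were mt-co3 (0.0944), sncga (0.33) and stmn4 (−0.0438) in Zn15 over Ctrl and psmd1 (−0.0537) in Zn15 over Zn10 with at least 200 genes, gpm6ab (0.0133), hsp70.3 (0.10) and jun (0.0199) in Zn15 over Zn10 by median of ratios, and hsp70.3 (0.0230) there without malat1.

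Lists are given as excesses. In Zn10 over Ctrl with at least 200 genes, metallothionein and MTF1 targets came to stand apart at −0.76 and apoptosis no longer did at −0.24. With a minimum of 5 UMIs, apoptosis (−0.19) and cholesterol synthesis (−0.16) no longer stood apart and synaptic vesicle machinery did (0.20), as it did by median of ratios (0.20). With a minimum of 100 UMIs, cholesterol synthesis reversed to 0.0137 and neurotrophic genes stood apart at 0.28. In Zn15 over Ctrl with at least 200 genes, inflammation (0.26), interferon response (0.40), antigen presentation (0.13) and glutamate receptors (−0.27) no longer stood apart, and glycolysis (−0.28), synaptic vesicle machinery (−0.67), neurotrophic (−0.31) and circadian genes (−0.29) did. With a minimum of 100 UMIs, inflammation (0.0457), glutamate receptors (−0.0399), transmitter synthesis (−0.26) and cell cycle (0.18) no longer did, and synaptic vesicle machinery (−0.33) and vessel and barrier genes (0.44) did. Antigen presentation no longer did with 5 UMIs (0.24), nor interferon response by median of ratios (0.32), without mitochondrial, ribosomal protein and haemoglobin genes (0.32) and without malat1 (0.32), where synaptic vesicle machinery did (−0.19).

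In Zn15 over Zn10 with at least 200 genes, endoplasmic reticulum stress (0.30), glycolysis (−0.40), cholesterol synthesis (0.42) and neurotrophic genes (−0.35) came to stand apart, and apoptosis (0.25), interferon response (0.39) and transmitter synthesis (−0.0116) no longer did. With a minimum of 100 UMIs, glycolysis (−0.31) and neurotrophic genes (−0.28) did, and interferon response (0.35), transmitter synthesis (−0.14) and cell cycle (0.17) did not. Glycolysis stood apart with 5 UMIs (−0.33). The heat shock list in dividing cell-like barcodes stood apart at halved resolution, at −0.27 in Zn10 and −0.30 in Zn15, where the class was a wider set of 529, 262 and 558 barcodes. In the main clustering it held 328, 183 and 360. The wider set may hold radial glia-like barcodes of cluster 10, most of which left their class at that resolution. The likeness of both zinc changes was 0.0897 with at least 200 UMIs and 0.107 with Ctrl split.

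Of 209 values of class shares with a ratio away from 1, 195 stayed within the interval of the main setting, 13 moved and 1 reversed. A share also counted as stayed where its new interval came to include 1, so lost calls are not tracked. Cluster 14 with at least 200 genes is such a case, at 1.51 (0.949 to 2.40) in Zn10 and 0.659 (0.382 to 1.12) in Zn15. Of the other 71, 69 stayed and 2 moved. Of 493 list values 453 kept side and call, 18 came to stand apart, 21 no longer did and 1 reversed. Of 58 heat shock values in classes 56 kept side and call, and of 21 medians over genes 10 stayed, 8 moved and 3 reversed. Of 2384 values of named genes 2193 stayed, 183 moved and 8 reversed, and of 348 gene values in classes 343 stayed and 5 moved.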

Other observations

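Microglia or macrophage-like barcodes of Zn10 differed from Ctrl in several lists. Inflammation genes there had an excess of 0.46 (percentile 99.4), with 8 of 12 measured members at least 1.5-fold higher, and antioxidant genes one of 0.51 (99.4). The inflammation list holds il1b, a leading gene of that cluster. Glycolysis genes stood at −0.51 (1.21) and amyloid, tau and neurodegeneration genes at −1.06 (0.365). Endoplasmic reticulum stress genes stood at −0.62 in GABAergic neuron-like and −0.45 in glutamatergic neuron-like barcodes of Zn10. These values were looked at after the whole-library lists and were not tested further.

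Synaptic vesicle genes in oligodendrocyte-like barcodes stood at −0.67 in Zn10 and −0.52 in Zn15. Immediate early genes in dividing cell-like barcodes of Zn10 stood at 0.48 (98.9).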
